A study of Mus musculus with 9 samples.

How the data were processed

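Gene expression was measured in 3 mouse stromal cell lines on 9 Affymetrix oligonucleotide arrays. Each line was hybridised once to each of 3 array types, MG-U74A, MG-U74B and MG-U74C, which carry different probe sets of the mouse transcriptome. Per the labels' protocols, total RNA was extracted with RNeasy columns and biotinylated cRNA was prepared from 6 ug of total RNA by the standard Affymetrix procedure. The values deposited by the authors are 1 linear intensity per probe set and array. The scanner software, background handling, summarisation of probes and scaling behind these intensities are not given in the sources used here. All deposited intensities were positive.

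The 3 arrays of a type did not share a common scale. Their means, trimmed by 2% at each end, differed by up to 61.1% on MG-U74A, 49.8% on MG-U74B and 49.7% on MG-U74C. A rule fixed before the data were examined called for quantile normalization of log2 intensities within an array type when these means differed by over 5%, and this was applied. Quantile normalization gives the 3 lines equal distributions, so a general shift of all transcripts between lines would be removed.

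The 3 tables hold 36899 probe sets, of which 198 are controls. Gene symbols came from the platform annotation. Of the remaining 36701 probe sets, 29131 had 1 symbol, 724 had several and 6846 had none; no gene was named from a probe set with several. Through gene identifiers in the RefSeq table of assembly GRCm38.p6, 0 symbols needed an update, and 99.8% of the symbols were present in that table. The same table was used for chromosome membership and gene order only. For gene-level values the probe set with the highest mean intensity over the 3 lines represented each of 15964 genes, whichever array type it was on, although levels on different array types are not on 1 scale.

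Values at or below a floor were set to the floor before ratios were formed. The floor was the median of all normalized values of the array type, 49.0 on MG-U74A, 26.6 on MG-U74B and 9.97 on MG-U74C. After the data were examined, a second level was computed from 34 control probe sets per array type that should find no target (antisense, unspiked bacterial and yeast sequences). The 95th percentile of their values was 39.1 on MG-U74A, 52.8 on MG-U74B and 61.5 on MG-U74C. The floor was thus below the background of MG-U74B and MG-U74C. The higher of both levels is called the detection level, and a fold against a line at or below it is given as "at least N-fold". No fold is given where both lines lie at or below it. In the 3 lines together, 14505 probe sets exceeded the control level in at least 1 line.

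With 1 array per line and array type there are no replicates, and no p-value, standard error or replicate SD can be given. The measurement error was described in 3 ways. Control probe sets repeated on all 3 array types gave an SD of the log2 ratio of 1.11 at intensities below 32, 0.36 from 32 to 128 and 0.20 above 128. These values compare the ratios that the 3 array types gave for the same control and do not cover separate cultures. Pairs of probe sets for 1 gene on the same array type, above the floor in both lines, gave a robust SD of 0.32 for AGM-s3-A9 against AGM-s3-A7 (1560 genes, 95% bootstrap interval 0.29 to 0.34), 0.35 for OP9 against AGM-s3-A7 and 0.37 for AGM-s3-A9 against OP9. For pairs of probe sets on different array types the robust SD was larger, at 0.38, 0.40 and 0.42 in the same order. Unchanged lines were also simulated 100 times with Gaussian errors. Their SD was taken, in 10 levels of intensity per array type, from all probe sets that share a gene and array type with another. Probe sets below the floor were included there, with values not raised to it.

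Probe sets were counted as higher or lower at a fold of at least 2. The counts shared by both comparisons against AGM-s3-A7 use the same AGM-s3-A7 arrays, so they were set beside the simulated count and beside the overlap of independent lists, which is the product of both counts divided by the number of probe sets that could have passed. For 24 gene lists fixed before the data were examined, the median log2 ratio of members above the floor in at least 1 line of the pair was computed for lists with at least 5 such members. Its percentile was taken among 10000 random lists of the same size matched on array type and on 5 levels of intensity. A list is said to stand apart at a percentile of at most 2 or at least 98, which describes these arrays and is no test across replicates.

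The genes named in the report follow a rule also fixed in advance. It takes, for each pair and direction, the 8 genes with the largest fold above the floor in both lines and up to 6 genes with the largest bounds of at least 8-fold against a line at the floor. It adds the 10 genes per direction with the largest smaller fold in both supportive lines against AGM-s3-A7, up to 4 members of each list that stands apart, and always Kitl, Cxcl12, Csf1, Vcam1 and Dlk1. Unnamed and predicted genes were passed over. The rankings by fold also left out genes with another probe set going at least 2-fold the other way, while members of lists were kept, among them Hoxb4 and Gbp2 for AGM-s3-A9 against OP9. Members with such a probe set also count in their lists. Ranking used the floor, while printed folds use the detection level. A selection from this set is described. Probe set suffixes that mark possible cross-hybridisation are pointed out for some genes only. Folds of other named genes also rest on such probe sets, among them Slit3, Rspo3, Gas5, Igf2, Igf1r, Cnn1 and Pparg.

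The procedure was tested on simulated data for AGM-s3-A9 against AGM-s3-A7 with 36701 probe sets. The changed probe sets were drawn only from those with a mean over 2-fold above the floor, so recovery of dimmer ones was not tested. Of 200 such probe sets changed 4-fold, 94.5% were recovered in their direction, and 4.70% of unchanged probe sets were called. With the control level as floor, 97.1% of the changed probe sets with a mean over 2-fold above it were recovered. Of the unchanged ones, 1.21% were called. In 92 tests of unshifted lists, 5 stood apart. The extracellular matrix list, shifted by a log2 ratio of 0.5, stood apart in 4 of 4 simulated data sets. No other list was shifted, so recovery of shorter lists was not tested.

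Alternatives were the values as deposited, scaling to the 75th percentile, floors at the 25th and 75th percentiles, a 3-fold threshold, probe sets without suffixes that mark possible cross-hybridisation, 1 probe set per gene, the median over a gene's probe sets, and random lists matched on array type alone. Added after the data were examined were the control level as floor, scaling to the hybridization controls, MG-U74A and MG-U74B alone, and lists without genes on chromosomes 6 and 15. For the scaling alternatives, list medians and gene ratios were taken relative to the median of all measured probe sets of the array type. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.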

Results

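The series compared 3 mouse stromal cell lines that differ in their capacity to support hematopoiesis. AGM-s3-A9 and AGM-s3-A7 were derived from the aorta-gonad-mesonephros (AGM) region, the part of the embryo in which hematopoietic stem cells first appear. AGM-s3-A9 supports hematopoiesis and AGM-s3-A7 does not. OP9, derived from the calvaria of newborn mice, is a supportive line. Each line was hybridised once to each of 3 array types, giving 9 arrays of 12488 (MG-U74A), 12477 (MG-U74B) and 11934 (MG-U74C) probe sets. The single array per line and type limits the precision, so differences are described by their size and set beside measurement error, without replicate error or p-values. The median deposited intensity ranged from 42.6 to 64.5 on MG-U74A, from 21.6 to 32.6 on MG-U74B and from 8.49 to 12.1 on MG-U74C. The ratio of 3' to 5' signal lay between 0.88 and 1.002 for Gapdh and between 1.07 and 1.26 for actin. On each array type the AGM lines correlated more closely with each other than either did with OP9. Across the probe sets of MG-U74A, which are not independent replicates, the Spearman correlation was 0.956 between the AGM lines, 0.928 between OP9 and AGM-s3-A7 and 0.933 between AGM-s3-A9 and OP9.

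The question put by the design is which transcripts distinguish the supportive lines from AGM-s3-A7. Kitl, which encodes stem cell factor, was at an intensity of 1243 in AGM-s3-A9, 438 in AGM-s3-A7 and 1270.1 in OP9, that is 2.84-fold and 2.90-fold higher in the supportive lines. The transcript of Csf1, the macrophage colony-stimulating factor gene, was 1.75-fold higher in AGM-s3-A9 and 2.51-fold higher in OP9 than in AGM-s3-A7. The arrays do not show whether a line makes functional protein from it. The brightest probe set of Cxcl12, a chemokine that retains hematopoietic stem cells, was high in all lines (4213 in AGM-s3-A9, 2711.5 in AGM-s3-A7 and 4860.2 in OP9). Its probe sets on MG-U74A disagreed on the size of the difference. One of them, with a suffix that marks possible cross-hybridisation, read 3101 in AGM-s3-A9 against 977 in AGM-s3-A7, and another read 2476 against 2735. Vcam1, an adhesion receptor for hematopoietic cells, was 1.31-fold higher in AGM-s3-A9 and 2.35-fold higher in OP9 on its brightest probe set. Of its 3 measured probe sets 1 reached 2-fold in OP9, the others reading 149 and 193 in OP9 against 122 and 98.9 in AGM-s3-A7. Dlk1, a member of the Notch pathway list, separated the supportive lines from each other, at 230 in AGM-s3-A9, 467 in AGM-s3-A7 and 1934 in OP9.

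Among the genes higher in both supportive lines, Spry1, an inhibitor of receptor tyrosine kinase signalling, was at 737 in AGM-s3-A9 and 933 in OP9 against 129 in AGM-s3-A7, or 5.73-fold and 7.25-fold higher. Il1rn, the interleukin-1 receptor antagonist, was 4.37-fold and 5.82-fold higher, and a second measured probe set did not reach 2-fold in OP9. Lpl, encoding lipoprotein lipase, was 4.32-fold higher in AGM-s3-A9 and 9.71-fold higher in OP9 on its brightest probe set. The heparan sulfate proteoglycan gene Gpc6 was 6.58-fold and 3.91-fold higher. Mest, an imprinted gene expressed from the paternal allele, was at or below the detection level in AGM-s3-A7 and at least 5.75-fold higher in AGM-s3-A9 and at least 38.8-fold higher in OP9. Epha7, Btbd3 and Mapkapk3 were likewise below the detection level in AGM-s3-A7, with bounds between 2.13-fold and 3.72-fold, that of Mapkapk3 on 1 of 2 probe sets. Wnk4 was at least 2.02-fold higher in AGM-s3-A9 and at least 1.24-fold in OP9, and for Slco6b1 all 3 lines lay at or below the detection level.

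Among the genes lower in both supportive lines, Dcn, which encodes the proteoglycan decorin, was at 1349 in AGM-s3-A7, 196 in AGM-s3-A9 and 21.2 in OP9, or 6.89-fold lower in AGM-s3-A9 and at least 27.5-fold lower in OP9. The matrix metalloproteinase gene Mmp3 was 6.61-fold lower in AGM-s3-A9 and at least 11.9-fold lower in OP9. Smoc2, which encodes a matricellular calcium-binding protein, was at 667 in AGM-s3-A7 and below the detection level in both supportive lines, at least 13.6-fold lower. Itgbl1, Fndc1, Aspn and Rab27b were likewise detected in AGM-s3-A7 alone, with bounds between 2.60-fold and 5.15-fold. Cpxm1 was 4.71-fold lower in AGM-s3-A9 and at least 4.89-fold lower in OP9. Retreg1 was 4.65-fold lower in AGM-s3-A9 and at least 31.2-fold lower in OP9. Hoxc8 was at least 3.48-fold lower in both, on 1 of 2 probe sets. Mest lies on chromosome 6 and Retreg1 and Hoxc8 on chromosome 15 in GRCm38.p6, chromosomes whose genes had median log2 ratios of 0.37 and -0.48 for OP9 against AGM-s3-A7.

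In all, 236 probe sets were at least 2-fold higher and 302 at least 2-fold lower in both supportive lines than in AGM-s3-A7, and by gene 116 named genes were higher and 134 lower. These counts use the median as floor. MG-U74C, where that floor lies below the background, gave 111 of the 236 and 142 of the 302. With the control level as floor MG-U74C gave 12 and 21. Because both comparisons use the AGM-s3-A7 arrays, simulated unchanged lines gave 205 shared higher probe sets on average and 376 lower ones, and independent lists would share 68.6 and 66.5. With the floor raised to the control level, 126 were shared higher, against 32.1 simulated and 29.6 for independent lists, and 156 were shared lower, against 59.3 and 25.02. The AGM-s3-A7 arrays cannot be split, so part of the excess over independent lists may come from the shared AGM-s3-A7 arrays. Counted in the same way at the control level, AGM-s3-A9 was higher than both other lines on 187 probe sets and lower on 73, and OP9 on 358 and 438.

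**Figure D1:**
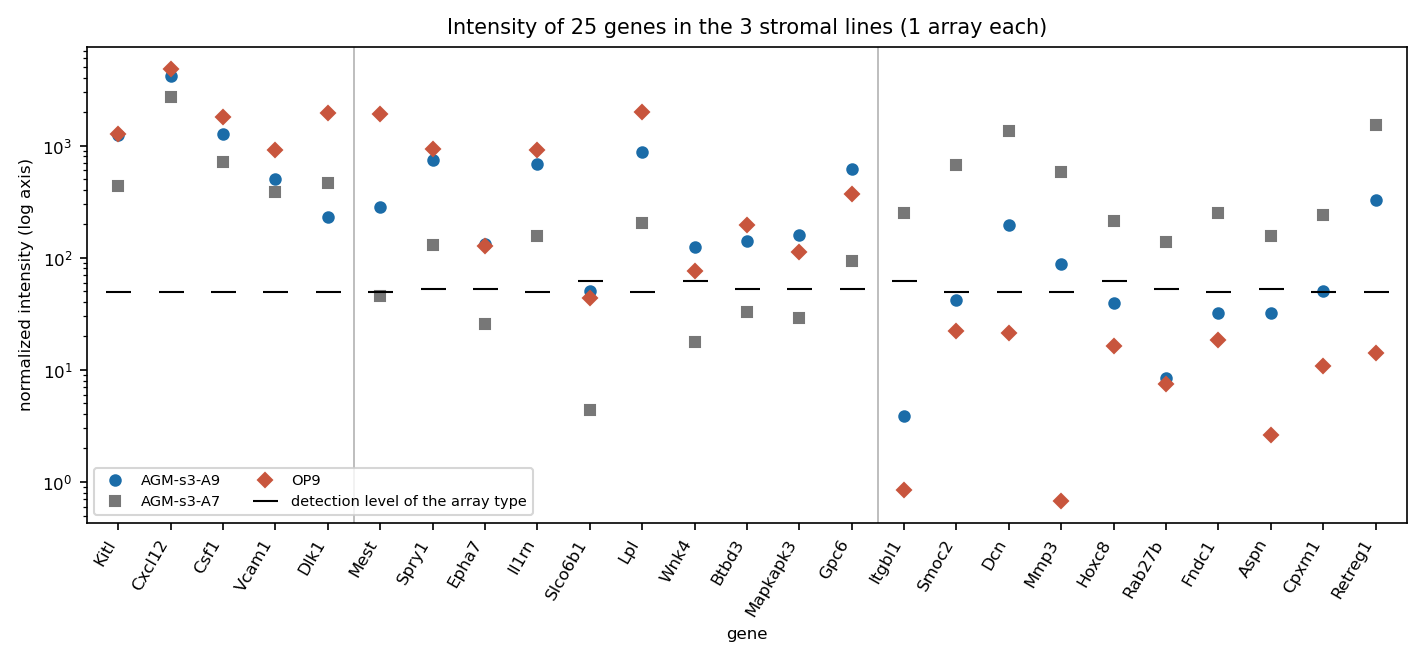
Normalized intensity (log axis) of 25 genes in the 3 lines, each symbol being 1 array; the dashes mark the detection level of the gene's array type, and vertical lines separate the 5 always-named genes, the 10 genes higher and the 10 genes lower in both supportive lines. Kitl reads 1243 and 1270.1 in the supportive lines against 438 in AGM-s3-A7, and Dcn reads 1349 in AGM-s3-A7 against 196 and 21.2.

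The comparison of AGM-s3-A9 with AGM-s3-A7 sets a supportive against a non-supportive line of the same embryonic region. Among the genes furthest above AGM-s3-A7, the secreted Wnt-binding protein gene Sfrp4 was at 817 against 112, or 7.31-fold higher, and the microfibril gene Mfap2 was 6.61-fold higher. Shisal1 was at least 12.5-fold higher, with both of its measured probe sets in that direction; it lies on chromosome 15, where the median between the AGM lines was -0.17. Ripk3, a kinase of necroptosis, was at least 4.87-fold higher, Il17rd at least 4.004-fold and Vit at least 3.20-fold. Besides Dcn, Mmp3, Smoc2 and Itgbl1, the lipocalin gene Lcn2 was lower, by 5.53-fold on 1 of 2 probe sets, and Ahnak2 was at least 3.98-fold lower. Lrrc15 was at or below the detection level in both lines.

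Of the 24 gene lists, 7 stood apart between these lines, where 0.96 would do so if members were drawn at random. Random draws do not allow for members of a list that vary together, so 0.96 may be too low. Members at least 2-fold apart are counted against the floor. Of 274 such counts in the lists that stood apart over the 3 comparisons, 7 concern genes at or below the detection level in both lines and 15 genes whose bound against it is under 2-fold. Hematopoietic cytokines and growth factors had a median log2 ratio of 0.31 over 22 measured members (percentile 99.8), with 4 members at least 2-fold higher and 0 lower. Those 4 were Kitl, Ccn3 (2.43-fold), Hgf (at least 2.62-fold) and Fgf10, whose bound against the detection level was 1.80-fold. The call was lost with a floor at the 25th percentile and with the median over a gene's probe sets. Interferon response and antigen presentation genes had a median of 0.52 over 33 members, with 5 at least 2-fold higher and 1 lower. The class I histocompatibility gene H2-K1 was 3.34-fold higher and Lgals3bp 2.498-fold on 1 of 2 probe sets. Both were read on probe sets whose suffix marks possible cross-hybridisation. Ifi202b was 2.20-fold higher and Oasl2 at least 2.66-fold. Cell cycle and DNA replication genes had a median of 0.52 over 44 members, 8 of them at least 2-fold higher and 0 lower. Among these were the proliferation marker Mki67 (2.60-fold) and the mitotic genes Aurkb, Cenpe and Tpx2, with bounds between 2.23-fold and 2.68-fold; for Mki67 and Aurkb 1 of 2 probe sets reached 2-fold. Hypoxia response and glycolysis genes had a median of 0.33 over 26 members, 5 at least 2-fold higher and 1 lower; 1 of the 5, Car9, was at or below the detection level in both lines. Epas1, which encodes the hypoxia-inducible factor 2 alpha, was 4.86-fold higher and the glycolytic enzyme gene Pfkl 2.24-fold higher. This call was lost with a floor at the 75th percentile and without genes of chromosomes 6 and 15. For the IGF axis the median was 0.59 and the mean 0.18 over 11 members. Higher by at least 2-fold were 2, Igf1 (2.12-fold on 1 of 4 measured probe sets) and Grb10 (2.06-fold on 1 of 3), and 2 were lower, Igfbp6 (2.75-fold) and Igf1r (2.17-fold); Igfbp6 and Igf1r are named for this pair after their values were seen. The call was lost on MG-U74A and MG-U74B alone and without probe sets of possible cross-hybridisation.

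Lower in AGM-s3-A9 were matrix remodelling enzymes and inhibitors (median -0.28 over 24 members, 1 at least 2-fold higher and 5 lower, 1 of these at or below the detection level in both lines) and cholesterol synthesis genes (median -0.42 over 19 members, with 0 reaching 2-fold in either direction). The collagenase gene Mmp13 was 2.54-fold lower, Mmp11 2.13-fold and the cathepsin gene Ctsk 2.06-fold on 1 of 2 probe sets. Sqle, the squalene epoxidase gene of the sterol pathway, was 1.81-fold lower and Sc5d 1.97-fold lower.

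Over all probe sets, 788 were at least 2-fold higher and 688 at least 2-fold lower in AGM-s3-A9 than in AGM-s3-A7. MG-U74C gave 373 of the 788 and 357 of the 688. Unchanged lines gave 868 and 873 in the simulation, and both observed counts lay below the lowest of the 100 simulated ones (790 and 811). The simulation thus overstates the error at this floor, and whether these counts exceed the error is left open. With the floor at the control level, 417 were higher against 209 simulated and 307 lower against 208. Of 67 genes whose brightest probe set differed by at least 2-fold, the second probe set on the same array type had the same direction in 82.1% and reached 2-fold in 31.3%. With the second probe set on another array type, a separate hybridisation, these were 80.65% and 21.5% of 93 genes.

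OP9 differed from AGM-s3-A7 more widely, in lines of different origin as well as different supportive capacity. Smooth muscle and contractile genes were lower in OP9, with a median of -1.09 over 21 members, 12 of them at least 2-fold lower and 0 higher. Cnn1, encoding calponin, was at 700.3 in AGM-s3-A7 and below the detection level in OP9, at least 14.3-fold lower. Acta2, the smooth muscle actin gene, was 4.58-fold lower on 1 of 2 probe sets, Mylk 4.20-fold and Tpm2 at least 8.31-fold. Extracellular matrix genes had a median of -0.62 over 46 members (4 higher, 16 lower), led by Dcn, Fmod (at least 17.1-fold), Fbln1 (8.10-fold) and the collagen gene Col3a1 (5.97-fold). Matrix remodelling genes had a median of -0.66 over 24 members (1 higher, 7 lower), with Mmp13 at least 56.5-fold and Plat, the tissue plasminogen activator gene, 10.4-fold lower. Chemokines and inflammatory mediators had a median of -0.68 over 18 members (2 higher, 7 lower). The acute phase gene Saa3 was at 4898 in AGM-s3-A7 and 14.8 in OP9, at least 99.9-fold lower, and the chemokine gene Ccl2 was 8.37-fold lower. Wnt pathway genes had a median of -0.61 over 29 members (3 higher, 10 lower, 1 of these at or below the detection level in both lines), with the Wnt antagonist gene Sfrp1 at least 16.7-fold lower. Hox genes had a median of -0.40 over 19 members (0 higher, 6 lower, 1 of these, Hoxb4, with another probe set at least 2-fold higher), including Hoxb6 (4.62-fold) and Hoxd8 (3.21-fold).

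Also lower in OP9 than in AGM-s3-A7 was the IGF axis, with a median of -0.45 over 10 members (1 higher, 3 lower) and with Igfbp6 at least 15.8-fold and Igf2 2.98-fold lower. The 1 higher, Grb10, is of unsettled direction: its brightest probe set, on MG-U74C, read 500.3 in OP9 against 67.9, and another, on MG-U74A, 5.58 against 119. BMP and TGF-beta pathway genes had a median of -0.29 over 34 members (4 higher, 6 lower), with Tgfbi at least 9.51-fold lower and Id1, an inhibitor of differentiation, 8.25-fold higher. Cell adhesion molecules had a median of -0.24 over 32 members (4 higher, 6 lower), with Ncam1 4.06-fold lower. Pericyte and mesenchymal stem cell markers had a median of -0.30 over 23 members (4 higher, 6 lower), with S100a4 8.09-fold lower and the transcription factor gene Ebf3 10.4-fold higher. Cholesterol synthesis genes had a median of -0.31 over 19 members (0 higher, 1 lower), the 1 being Cyp51 (2.45-fold). The IGF axis lost its call with a floor at the 25th percentile and with scaling to the 75th percentile or to hybridization controls, and the BMP and cholesterol lists with the median over a gene's probe sets. The adhesion and pericyte lists lost theirs with a floor at the 75th percentile, and the adhesion list also with hybridization control scaling. Among genes in none of the lists, Serping1, the C1 inhibitor gene of the complement system, was 30.7-fold lower, Apoe at least 40.5-fold lower on 1 of 2 probe sets, Plac8 at least 54.3-fold, Slit3 at least 17.2-fold, Lmo7 17.6-fold and Amigo2 15.9-fold.

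Higher in OP9 was the list of senescence, p53 and imprinted growth regulators, with a median of 1.03 over 17 members, 10 of them at least 2-fold higher and 2 lower. Its leading members were the imprinted genes Mest and Meg3 (at least 14.2-fold on the brightest of 4 probe sets) and the p53 targets Cdkn1a (6.74-fold) and Sesn2 (at least 5.31-fold). Cell cycle and DNA replication genes had a median of 0.53 over 41 members (11 higher, 0 lower), with the cyclin genes Ccnd2 and Ccnd1 3.36-fold and 3.12-fold higher. Chondrocyte markers had a median of 0.61 over 8 members (4 higher, 1 lower), of which Cnmd among the higher and the 1 lower gene were at or below the detection level in both lines, with the cartilage transcription factor gene Sox9 5.20-fold higher on the brightest of 5 measured probe sets. Adipocyte markers had a median of 0.33 over 20 members (7 higher, 3 lower), among them Lpl, the transcription factor genes Pparg (4.39-fold) and Cebpa (4.24-fold) and Adipoq (at least 4.08-fold). Notch pathway genes had a median of 0.34 over 18 members (5 higher, 0 lower), with Dlk1 4.14-fold on 1 of 2 probe sets, the ligand gene Jag1 3.67-fold on 2 of 3 and Notch3 2.81-fold higher. The calls for adipocyte markers and for the Notch pathway were each lost under 7 of 11 alternatives, among them the values as deposited and 75th percentile scaling. That for chondrocyte markers was lost under 3 of 10, among them the control level as floor. The growth arrest transcript Gas5 was 13.9-fold higher in OP9, and Ptx3, a member of the inflammatory list, was 9.66-fold higher on 1 of 2 probe sets. Rspo3, which encodes a Wnt agonist, was at least 6.03-fold higher and Mtap at least 5.85-fold higher.

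In total 16 of 24 lists stood apart between OP9 and AGM-s3-A7. At least 2-fold higher in OP9 were 1337 probe sets and 1484 were lower, against 868 and 870 in simulated unchanged lines. MG-U74C gave 633 of the 1337 and 658 of the 1484. With the control level as floor the counts were 687 and 790 against 209 and 210.5. Of the OP9 and AGM-s3-A7 calls, 47.4% were higher in OP9, which became 38.3% with the values as deposited and 64.1% with scaling to the hybridization controls. Among the named genes at least 2-fold apart, 9 of 57 lower in OP9 lie on chromosome 15 in GRCm38.p6 (Amigo2, Retreg1, Hoxc8, Igfbp6, Fzd6, Acvrl1, Sdc2, Fbln1 and Ly6e), and 5 of 41 higher in OP9 lie on chromosome 6 (Vamp5, Mest, Pparg, Ccnd2 and Mad2l1). Over all genes of the autosomes and X, with the control level as floor, 73 of 543 lower lie on chromosome 15 and 87 of 467 higher on chromosome 6.

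AGM-s3-A9 and OP9 share supportive capacity and differ in origin. Of 23 lists with enough members, 10 stood apart between them. Smooth muscle and contractile genes were higher in AGM-s3-A9, with a median of 1.10 over 21 members, 11 of them at least 2-fold higher and 0 lower. Actg2 was 6.68-fold higher and Cnn1 at least 12.2-fold higher. Extracellular matrix genes had a median of 0.63 over 46 members (15 higher, 4 lower), with Fmod at least 24.2-fold and the fibrillin gene Fbn2 at least 6.82-fold higher, with all 4 measured probe sets in that direction. Matrix remodelling genes had a median of 0.45 over 24 members (6 higher, 1 lower), with Mmp9 at least 11.5-fold higher. Wnt pathway genes had a median of 0.55 over 30 members (10 higher, 1 lower; 1 of the 10 was at or below the detection level in both lines, and 5 of the 10 and the 1 lower had bounds under 2-fold), with Sfrp1 at least 54.2-fold, Sfrp4 at least 16.7-fold and Sfrp2 6.64-fold higher. The IGF axis had a median of 0.80 over 11 members (4 higher, 2 lower), with Igfbp2 at least 18.2-fold higher and Grb10 counted as lower although 2 of its 3 measured probe sets were at least 2-fold higher, and chemokines and inflammatory mediators 0.71 over 19 members (8 higher, 2 lower), with Ccl2 8.85-fold higher. Hox genes had a median of 0.67 over 16 members (7 higher, 1 of them at or below the detection level in both lines, and 0 lower), with Hoxb6 4.51-fold, Hoxa5 3.53-fold and Hoxb2 3.01-fold higher. Interferon response and antigen presentation genes had a median of 0.30 over 35 members (10 higher, 0 lower), with Ifi47 at least 6.82-fold and Ifi204 3.95-fold higher. Cell cycle genes had a median of 0.20 and a mean of 0.0012 over 44 members (0 higher, 3 lower). This call was lost with a floor at the 75th percentile and with the median over a gene's probe sets.

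The senescence, p53 and imprinted growth regulator list was lower in AGM-s3-A9 than in OP9, with a median of -1.25 over 16 members (1 higher, 9 lower). Mest was 6.75-fold lower, Gadd45a 6.67-fold lower and Meg3 at least 14.2-fold lower. Gas5 was 21.7-fold lower, Cped1 14.3-fold lower on the brightest of 3 probe sets and Dlk1 8.42-fold lower. Serping1 was 42.3-fold higher in AGM-s3-A9, Apoe at least 43.7-fold on 1 of 2 probe sets, Ccn3 at least 33.1-fold, Slit3 at least 22.97-fold and the natriuretic peptide receptor gene Npr3 9.34-fold higher on the brightest of 4 probe sets. Of the named genes, 6 of 43 higher in AGM-s3-A9 than in OP9 lie on chromosome 15 (Npr3, Ccn3 and Fbln1 among them) and 5 of 16 lower lie on chromosome 6 (Mest, Gadd45a and Cped1 among them). With the control level as floor, 46 of 376 measured chromosome 15 genes were at least 2-fold higher in AGM-s3-A9 than in OP9 and 6 were lower. On chromosome 6, 83 of 487 were lower and 16 higher. Their shares among all genes at least 2-fold apart were not computed for this pair, so whether the named genes exceed those shares stays open. The 43 include Hoxb4 and Gbp2, each with another probe set at least 2-fold lower. There were 1575 probe sets at least 2-fold higher and 1392 lower in AGM-s3-A9 than in OP9, against 869 and 868 simulated, and 843 and 653 with the control level as floor, against 210 and 209. MG-U74C gave 705 of the 1575 and 682 of the 1392. The share of higher calls, 53.1%, became 39.5% with scaling to the hybridization controls.

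Markers of blood cells, endothelium, epithelium, urogenital ridge and gonad, and osteoblasts did not stand apart under the main setting in any comparison with enough members. A call was gained for endothelial markers in AGM-s3-A9 against OP9 with the values as deposited (median 0.58) and for blood cell markers in OP9 against AGM-s3-A7 on MG-U74A and MG-U74B alone (median -0.49 over 7 members). Blood cell markers had 8 of 37 listed genes above the floor and medians of 0.00, -0.14 and -0.11 for AGM-s3-A9 against AGM-s3-A7, OP9 against AGM-s3-A7 and AGM-s3-A9 against OP9. For endothelial markers, 5 of 26 listed genes were measured, with medians of 0.15, -0.42 and 0.50. Epithelial markers had medians of -0.23, -0.21 and 0.02, and urogenital ridge and gonad markers -0.13, -0.05 and 0.14. Osteoblast markers, with 5 measured genes, had medians of 0.29 for AGM-s3-A9 and 0.50 for OP9 against AGM-s3-A7, with too few measured for the third pair. Median and mean differed in sign for blood cell markers in AGM-s3-A9 against AGM-s3-A7 (mean -0.03) and against OP9 (mean 0.12) and for urogenital markers in AGM-s3-A9 against OP9 (mean -0.13).

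The remaining lists did not stand apart under the main setting. Between the AGM lines the medians were -0.07 for the Notch pathway (mean 0.03), 0.07 for the Wnt pathway, 0.16 for the BMP and TGF-beta pathway, -0.06 for adhesion molecules and 0.06 for extracellular matrix. They were -0.06 for adipocyte markers (mean 0.17), 0.10 for chondrocyte markers, 0.01 for smooth muscle genes and -0.07 for pericyte markers (mean 0.02). Hox genes had a median of -0.04, chemokines 0.21 and the senescence, p53 and imprinted list -0.07. Chemokines gained a call with 75th percentile scaling (0.29), without probe sets of possible cross-hybridisation (0.25) and with the control level as floor (0.24). The senescence list gained one with a floor at the 25th percentile (-0.34), the BMP and TGF-beta pathway with the median over a gene's probe sets (0.21) and chondrocyte markers on MG-U74A and MG-U74B alone (0.58). For OP9 against AGM-s3-A7 the medians were 0.23 for hematopoietic cytokines and growth factors (4 of 21 higher, 3 lower, 1 of these at or below the detection level in both lines), 0.06 for interferon genes (mean -0.09) and -0.01 for hypoxia and glycolysis. The hematopoietic list gained a call with a floor at the 75th percentile (median 0.64 over 11 members, percentile 99.97) and with the control level as floor (0.44 over 19 members, percentile 99.75). For AGM-s3-A9 against OP9 they were -0.03 for hematopoietic cytokines and growth factors (mean 0.27), -0.24 for the Notch pathway, 0.20 for the BMP and TGF-beta pathway and -0.09 for adhesion molecules (mean 0.20). Adipocyte markers had a median of -0.25 there, chondrocyte markers -0.35, pericyte markers 0.18, cholesterol synthesis 0.14 and hypoxia and glycolysis 0.19. Calls were gained there for the Notch pathway with the values as deposited (-0.32) and a floor at the 75th percentile (-0.59), and for the BMP and TGF-beta pathway with the control level as floor (0.27). Chondrocyte markers gained one with the median over a gene's probe sets (-0.44) and hybridization control scaling (-0.41), and hypoxia and glycolysis without probe sets of possible cross-hybridisation (0.42) and on MG-U74A and MG-U74B alone (0.23).

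**Figure D2:**
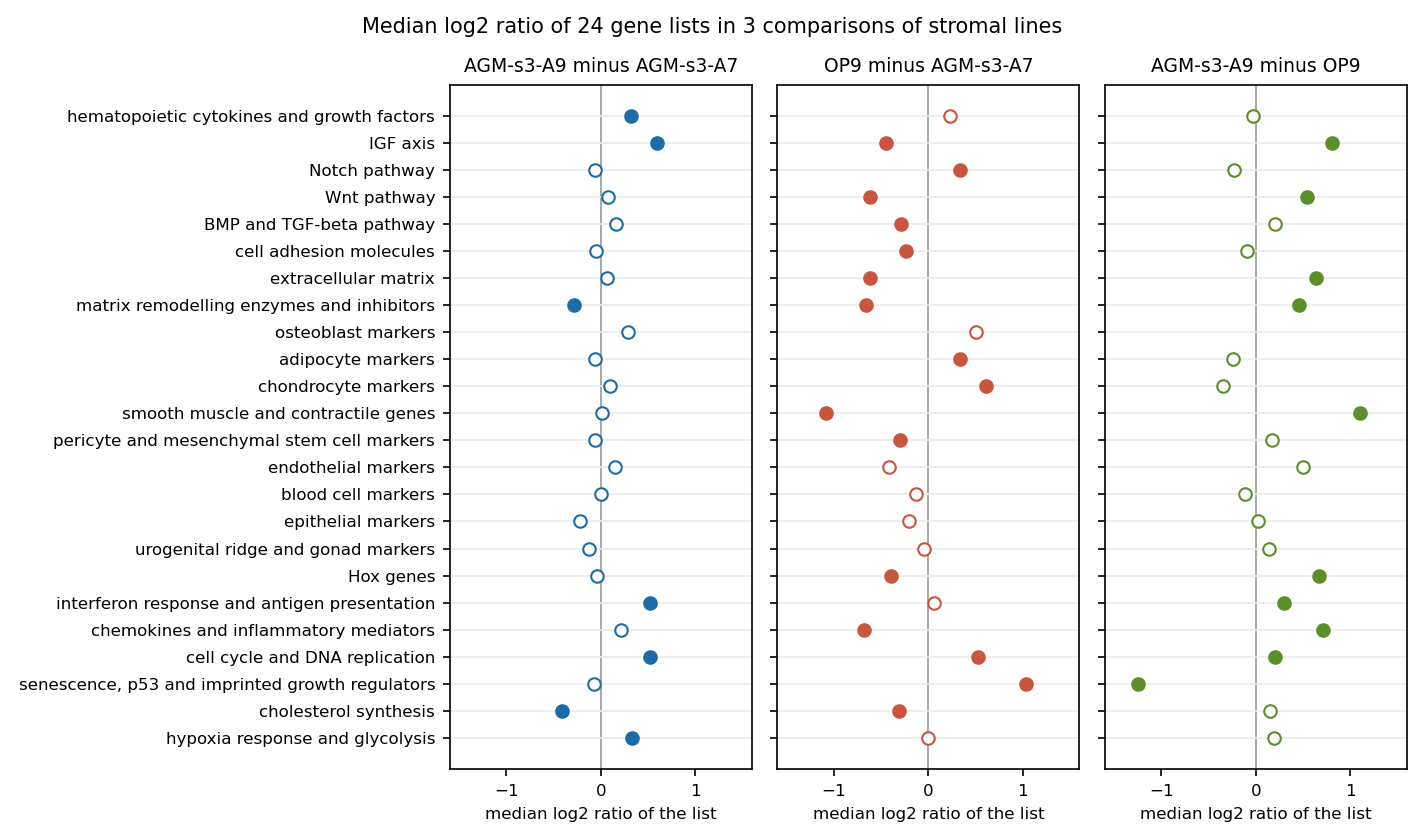
Median log2 ratio of the measured members of 24 gene lists in the 3 comparisons; filled points stand apart from random lists, open points do not, and a list with under 5 measured members has no point. Smooth muscle and contractile genes lie at -1.09 for OP9 minus AGM-s3-A7 and at 1.10 for AGM-s3-A9 minus OP9, and at 0.01 between the AGM lines.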

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

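The result in this part was chosen after the data were examined, and no explanation for it was tested. It concerns a control probe set that no comparison of genes uses and that was above the detection level in both lines compared on each array type, with the normalized values averaged over the 3 array types. The control probe set for the B1 repeat, a short interspersed element transcribed in many mouse RNAs, was higher in AGM-s3-A7 than in OP9 by a log2 ratio of 0.86 ± 0.06 (SD over 3 array types), with mean intensities of 3126 in AGM-s3-A7, 2883 in AGM-s3-A9 and 1721 in OP9. The 3 array types carry separate hybridisations of 1 line each, so this SD does not cover differences between cultures.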

How the results depend on the processing

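The settings with the control level as floor, hybridization control scaling, MG-U74A and MG-U74B alone and lists without chromosomes 6 and 15 were chosen after seeing the data. Counts are given in the order higher and lower in AGM-s3-A9 than in AGM-s3-A7, higher and lower in OP9 than in AGM-s3-A7, higher and lower in AGM-s3-A9 than in OP9, and higher and lower in both supportive lines. They moved by over 1.5 times with the floor at the 25th percentile (2220, 2084, 3144, 3250, 3343, 3238, 804 and 924) and at the 75th percentile (236, 206, 438, 558, 572, 456, 60 and 100). They moved likewise with a 3-fold threshold (201, 161, 413, 559, 635, 401, 46 and 77), with the control level as floor (417, 307, 687, 790, 843, 653, 126 and 156), with 1 probe set per gene (416, 337, 691, 774, 847, 703, 125 and 150) and on MG-U74A and MG-U74B alone (415, 331, 704, 826, 870, 710, 125 and 160); the last 2 settings test fewer probe sets. With the values as deposited, 1706 and 1622 probe sets were higher and lower in AGM-s3-A9 than in AGM-s3-A7, 2154 were lower in AGM-s3-A9 than in OP9 and 674 were lower in both supportive lines. Hybridization control scaling gave 2038 higher in OP9 than in AGM-s3-A7 and 361 higher in both supportive lines. The median ratio of all measured probe sets then differed from 0, by -0.67 to 0.69 over pairs and array types as deposited and by -0.51 to 0.39 with hybridization controls, and list and gene values under these scalings are relative to it; the cause of the moved counts was not tested. The other counts under these scalings, and all 8 under 75th percentile scaling and without probe sets of possible cross-hybridisation, stayed within 1.5 times. The error between probe sets of 1 gene, 0.32, was 0.40 and 0.26 with floors at the 25th and 75th percentiles, outside its 95% bootstrap interval of 0.29 to 0.34, a criterion set after these values were seen. The number of list medians apart, 33 over the 3 comparisons, ranged from 29 to 34 under the alternatives, and the calls held under each alternative that gave a value for 4 of 7 lists between the AGM lines, 8 of 16 for OP9 against AGM-s3-A7 and 9 of 10 for AGM-s3-A9 against OP9. Of 38 list medians not apart, 11 gained a call under at least 1 alternative, given with the lists. The chondrocyte list had too few members with a floor at the 75th percentile. Of 1380 gene ratios under alternatives, 306 moved by at least the SD of control probe sets at their intensity, 90 away from 0 and 216 towards it, of which 146 with the floor at the 75th percentile. Among called genes 0 changed sign, and 64 of 1248 ratios dropped under 2-fold. Settings that only move the floor cannot change a sign, so the 0 speaks for the scaling alternatives alone. Low signal limits MG-U74C most, where 13.5% of values exceeded the control level. No paired analysis was possible because each group holds 1 array.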

Other observations

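The tests by array type and in bright genes in this part were written before their results were seen; the other tests were chosen after the result was seen. Transcripts of the Y chromosome, singled out after their values were seen, were mostly below the detection level. Eif2s3y was at 143 in AGM-s3-A9, 6.58 in AGM-s3-A7 and 67.9 in OP9, and Kdm5d on its brightest probe set was above the detection level in OP9 alone, at 146. Both values come from probe sets whose suffix marks possible cross-hybridisation. The other Kdm5d probe sets, at 52.05 and 11.3 in OP9, lay below the detection level. Uty, at 49.05 in AGM-s3-A9, only just reached the detection level of 49.01 there and lay below it in the other lines. Sry, Uba1y, Rhoay-ps3, Tspy-ps and the X-linked Xist were below the detection level in all 3 lines.

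Genes were grouped by chromosome in GRCm38.p6, with the control level as floor. Between OP9 and AGM-s3-A7, the 381 measured genes of chromosome 15 had a median log2 ratio of -0.48 and those of chromosome 6 (492 genes) a median of 0.37, both outside 10000 matched random lists. Such medians were common, as 14 of 20 chromosomes stood apart for this pair, 9 between the AGM lines and 13 between AGM-s3-A9 and OP9. Of the chromosome 15 genes, 80.3% were lower in OP9 and 73 were at least 2-fold lower, out of 543 such genes on the autosomes and X. Chromosome 13 followed at -0.25 (311 genes). AGM-s3-A9 lay between the other lines on chromosome 15, with medians of -0.17 against AGM-s3-A7 and 0.27 against OP9, and below both on chromosome 12, at -0.20 and -0.31. Between the AGM lines, chromosomes 2, 4 and 14 had medians of 0.23, 0.21 and 0.19 and chromosome 8 a median of -0.21.

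For chromosome 15 in OP9 against AGM-s3-A7, a fault of a single array type is argued against, since the highest of the 3 medians by array type was -0.31. Noise of dim genes is argued against as well, since genes that were bright in both lines had a median of -0.50. With the chromosome split at its middle gene, both parts were lower, the higher of their medians being -0.46. A hypothesis is that the lines differ in chromosome copy number, as cultured lines often do, which may lower transcripts along the whole chromosome. DNA was not measured, so a regulatory difference spread along the chromosome stays open, as does the different origin of the lines.

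Cdkn2a, Cdkn2b and Mtap, neighbouring genes on chromosome 4 singled out, like the genes around them, after their values were seen, of which the first 2 encode inhibitors of cell cycle kinases, were below the detection level in both AGM lines and above it in OP9. Their intensities in OP9 were 136, 100.5 and 309, so OP9 was at least 2.76-fold, 2.05-fold and 5.85-fold higher. Neighbours on the chromosome cannot decide whether signal failed on the AGM arrays, since the positions of probe sets on the arrays were not examined. The 3 genes were read on MG-U74A (Cdkn2a and Cdkn2b) and MG-U74B (Mtap), which are separate hybridisations. On MG-U74A, 1 of 6 neighbouring measured genes, Klhl9, was at least 2-fold above the detection level in both AGM lines. It read 269 in AGM-s3-A9, 242 in AGM-s3-A7 and 251 in OP9. On MG-U74B 0 neighbours were measured. With Gm13290 and Plaa, 3 of the 6 lay above the detection level of 49.01 in both AGM lines. Those 2 were nearer to it. Gm13290 read 77.4 in AGM-s3-A9, 63.55 in AGM-s3-A7 and 67.65 in OP9, and Plaa 76.6, 72.3 and 87.0. Tusc1, the next measured gene after the locus, showed the opposite, at 170 and 150 in the AGM lines and 1.52 in OP9. Loss of the locus in the AGM lines is a possible explanation, since no probe set of the 3 genes there exceeded an intensity of 24.8, but silencing would give the same and both cannot be told apart from RNA.

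The shared difference of both supportive lines from AGM-s3-A7 depends on the level above which probe sets are counted. With the median as floor, the 236 probe sets shared higher lie within the simulated range for unchanged lines (166 to 244) and the 302 shared lower lie below theirs (336 to 418), so the simulation overstates the error there and decides nothing about measurement error on the shared AGM-s3-A7 arrays. With the control level as floor, 126 shared higher exceed the highest simulated count of 53 and 156 shared lower exceed the highest of 82, which argues against Gaussian error of the simulated size as the whole account there; heavier tails were not simulated. A culture difference of AGM-s3-A7 and its lack of supportive capacity stay open, since 1 line stands for the non-supportive state. AGM-s3-A7 was not the line furthest apart: at the control level it was higher than both other lines on 156 probe sets and lower on 126, AGM-s3-A9 on 187 and 73, and OP9 on 358 and 438.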
